A study of Mus musculus with 5 samples.

How the data were processed

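The series holds ATAC-seq of the anterior forelimb pair of 5 single mouse embryos at stage E11.5, with 2 control and 3 mutant libraries. Groups were taken from the genotype in the labels. Replicate numbers follow the order of the samples and pair nothing. Each library came from a separately genotyped embryo, so the spread between libraries includes the spread between animals.

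Per the submitters' processing notes, reads were converted with bcl2fastq 2.20.0, aligned with Bowtie2 2.3.5 to mm10 and peaks were called with MACS2, whose version is not given in the sources used here. The MACS2 options, the removal of duplicates and the shift of reads by the cut site of the transposase are not given in the sources used here either. A missing shift would move peak borders by a few bases, and retained duplicates would raise the pileup of every library. The authors deposited 1 peak list per library, not pooled, with no header. Per the labels and the MACS2 layout, each deposited row gives start and end positions and a summit (other values, in base pairs), a display score, a fold enrichment ratio over background, and the −log10 p-value and −log10 q-value at the summit. The authors' fold was computed within each library and is not scaled between libraries, so it served to rank and filter peaks within a list. The lowest deposited −log10 q-value was 1.50 to 1.69. The deposited score was not used further.

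The fold values of each list lay on an even grid (100% within 0.02 of a step), as (pileup + 1) divided by (background + 1) with 1 background per library gives. The Poisson p from that pileup and background matched the deposited −log10 p-value to within 1.4e-05 in every list, for values under 100. The background is thus the mean number of fragments expected per position, a relative measure of depth if fragments were extended alike in all libraries. It was 4.77 and 6.42 in the controls and 5.48, 5.09 and 4.95 in the mutants. Read numbers are unknown, so no counting interval was formed for single peaks. The lowest fold in a list was 2.29 to 2.52, so a region without a peak can still be accessible below that level. This floor was 2.43 and 2.29 in controls 1 and 2 and 2.47, 2.46 and 2.52 in mutants 1, 2 and 3. It thus lay slightly higher in each mutant than in either control.

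Peaks on chromosomes 1 to 19 and X were used. Peaks that shared at least 1 bp were merged over the 5 lists into regions, and a region was present in a library that had a peak in it. Genes came from the RefSeq table of assembly GRCm38.p6, the same coordinates as mm10, with 21887 protein-coding genes. The table gives no strand and no exons, so start and end of a gene could not be told apart. The planned class of promoters became gene-end regions, within 1 kb of either end of a gene, and other regions were called distal. Each region went to the gene with the nearest end within 100 kb of the strongest summit, in place of the nearest start. This assigns a distant enhancer to the nearest gene, which need not be its target. Of 45158 regions in both controls, 38919 were assigned, to 15158 genes.

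Peak numbers, covered length, median width, gene-end share and background were compared between genotypes with an exact two-sided permutation test of the difference of means, for which 2 against 3 libraries give a smallest p of 0.2. Regions in both controls and no mutant, and in all mutants and no control, were counted for each of the 10 splits of the libraries. Strength was the mean percentile of the authors' fold within the 2 control lists, in 10 deciles. Absence of distal and gene-end regions was compared with a Cochran-Mantel-Haenszel test stratified by decile, with 95% intervals. The 23 gene lists, with 372 symbols, all matched, were fixed before the data were examined. For each list, the mean over its regions of absence from all mutants minus the rate of the stratum (decile by class) was set against 10000 random gene lists matched on regions per gene, drawn with replacement (a permutation test over genes), two-sided, with a smallest p of 0.0002 and Benjamini-Hochberg adjustment over the lists. These tests compare regions or genes of these libraries, not embryos.

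Named genes followed a rule fixed before the data were examined: Smarcc1, every Hedgehog target with a region in both controls, the nearest gene of the 10 strongest regions found in 1 genotype alone, the 5 genes with the largest and the 5 with the lowest sum of absence over expectation among genes with at least 5 regions, and up to 4 members with the most absent and up to 2 with the most present regions of each list. Of these members only some are named. A few genes that the rule takes are not reported here. A gene in several lists is named where any list or rule takes it.

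The list test and the odds ratio were tested on simulated data made from the 45158 regions, with absence drawn for each region on its own. Simulated lists took only genes with several regions. With no added absence 5 of 100 lists of 20 genes passed the unadjusted threshold of 0.05, with 10 and 20 points added 61 and 100 did, and a simulated odds ratio of 5 came back as 5.25 (4.91 to 5.61). Alternatives were a −log10 q-value of at least 5 or 10, equal list lengths, a fold of at least 5, all chromosomes, summit windows of 100 bp on either side, an asymmetric threshold, gene assignment within 20 kb or by gene body with 5 kb flanks (planned for the upstream side alone, taken on both sides for want of strand), a 2 kb gene-end width, no stratification, absence from at least 2 mutants, and each library left out in turn. Without stratification, Fisher's exact test over regions replaced the permutation over genes for the gene lists. That setting thus also counts the regions of a gene as independent. The test of 27 motifs needed a genome sequence and was not run, and GC content was not analysed here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.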

Results

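Chromatin accessibility was profiled by ATAC-seq, in which a transposase cuts open chromatin, in the anterior forelimb bud of single mouse embryos at stage E11.5 (40 to 48 somites). Each of the 5 libraries came from 50K cells of the forelimb pair of 1 genotyped embryo. There were 2 controls, which carried the conditional Smarcc1 allele without Cre, and 3 mutants, in which Prx-Cre, active in limb mesenchyme, acts on the same allele. Smarcc1 encodes BAF155, a core subunit of the BAF (SWI/SNF) chromatin remodelling complex. The series asks whether this complex is needed for repression by GLI proteins, the transcription factors of Hedgehog signalling, and the anterior limb bud is where the GLI3 repressor prevails. The files are peak lists, so each measurement is the presence or absence of a called peak. The read depth is unknown, but a background level of 4.77 and 6.42 fragments per position lay behind the lists of controls 1 and 2, and of 5.48, 5.09 and 4.95 behind those of mutants 1, 2 and 3.

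At the targeted gene, Smarcc1 (chromosome 9, 110132024 to 110240178, mm10), a region at 1 gene end (110130829 to 110132866) held a peak in all 5 libraries. A region within the gene body (110205938 to 110206444) held a peak in both controls and in mutants 1 and 2 and none in mutant 3. A peak at a gene end does not measure deletion of the conditional exons, so the locus does not check the genotype labels.

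Fewer peaks were called in each mutant limb bud than in either control, and most of the difference lay away from gene ends. Controls held 64646 ± 6100 peaks (SD, n = 2) and mutants 35569 ± 7863 (SD, n = 3), a mean 45.0% lower. Peaks away from gene ends, called distal here, numbered 48414 ± 5778 in controls and 21009 ± 6562 in mutants, 56.6% lower. Peaks within 1 kb of either end of a protein-coding gene, called gene-end, numbered 16232.5 ± 322 in controls and 14560 ± 1301 in mutants, 10.3% lower. All 3 mutants lay below both controls in each of these counts, and the exact two-sided permutation test gave p = 0.2 for each, the smallest value that 2 against 3 libraries allow. Gene-end peaks made up 25.2% ± 1.9 of the control lists and 41.8% ± 6.0 of the mutant lists (exact permutation p = 0.2, n = 2 and 3). When each control list was shortened to its strongest peaks at the length of each mutant list, a comparison chosen after seeing the data, the control share was 32.2% to 43.8% and the mutant lists stood on average 4.71 percentage points higher. Covered sequence was 43.8 ± 5.1 Mb in controls and 25.2 ± 6.0 Mb in mutants (exact permutation p = 0.2, n = 2 and 3). Median peak widths were 477 ± 9.9 bp in controls and 505 ± 23 bp in mutants (exact permutation p = 0.4, n = 2 and 3), but with every list at equal length the mutant minus control difference turned from 27.7 to -270.5 bp (exact permutation p = 0.2, n = 2 and 3). Background levels were 5.59 ± 1.17 in controls and 5.17 ± 0.28 in mutants (SD, exact permutation p = 0.8, n = 2 and 3). The difference of -0.42 was smaller than the spread of the controls but larger than that of the mutants.

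**Figure D1:**
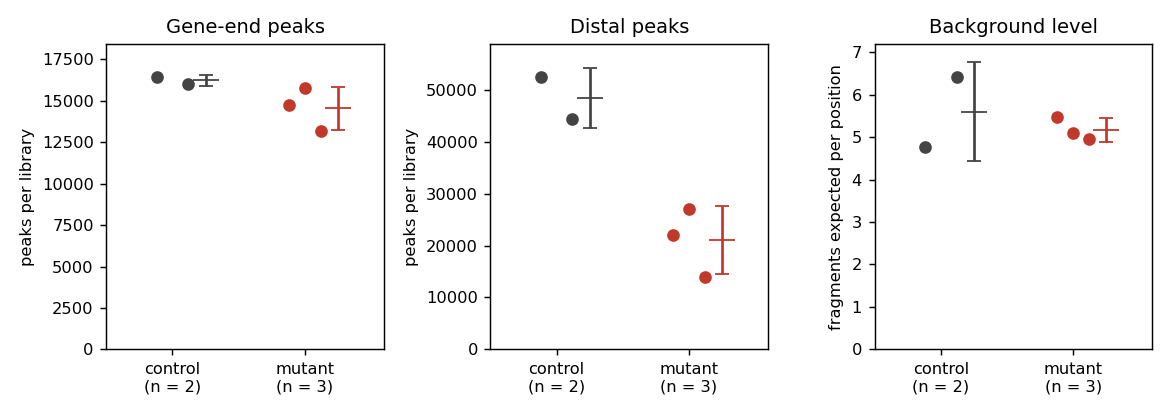
Gene-end peaks, distal peaks and the background level (fragments expected per position) of each library, with points for libraries, dashes for the group mean and bars for 1 SD (n = 2 controls, 3 mutants). The mutants hold 14016 to 27032 distal peaks against 44328 and 52499 in the controls, while gene-end peaks lie between 13178 and 16460 in all 5 libraries.

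Merging the 5 lists gave 86713 regions, of which 19579 held a peak in every library. Both controls shared 45158 regions, and 13743 of these (30.4%) had no peak in any mutant. Of the 13743, 13094 were distal and 649 gene-end. In the other direction, only 42 regions held a peak in all 3 mutants and in neither control. Among the 10 ways to divide the libraries into 2 and 3, the highest count for any other pair was 1393, and the counts for the other trios ran from 70 to 2668. With 10 splits no share under 0.1 can be reached, so neither count can pass a test at 0.05. The number of regions found in the mutants alone depended on list length: with every list shortened to 27194 peaks it was 677, against at most 580 for another trio, while 2976 regions were found in the controls alone, against at most 985 for another pair. Leaving out 1 library moved the control-only count to between 14399 and 31736, the highest without control 2 and the next, 23738, without control 1. The mutant-only count without 1 library was 164 and 155 (controls 1 and 2) or 129, 114 and 440 (mutants 1, 2 and 3). The Jaccard index of covered bases was 0.602 between the controls, 0.556 ± 0.054 (SD, 3 pairs) among mutants and 0.460 ± 0.063 (SD, 6 pairs) between genotypes, though mutants 2 and 3 (0.500) lay below control 2 with mutant 1 (0.527) and with mutant 2 (0.510). As the share of the shorter list's peaks with at least 1 bp in the longer list the order of the means was the reverse, 80.6% between the controls, 84.9% among mutants (79.2% to 88.1%) and 86.1% between genotypes (75.0% to 94.3%), so the order depends on the measure.

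None of the 10 strongest control regions absent from all 3 mutants lay at a gene end. Fold values here are the peaks' own values in the authors' lists. The first by strength (chromosome 12, 117486277 to 117487091) lay 29.9 kb from an end of Rapgef5, a guanine nucleotide exchange factor of RAP proteins, with a fold of 12.1 in control 1 and 9.16 in control 2. The next lay within Astn2, a gene of neuronal migration (chromosome 4, 66025022 to 66026074), with no gene end within 100 kb, and had folds of 11.4 and 9.03. A region within Etv1, an ETS transcription factor (chromosome 12, 38843539 to 38844361), had folds of 9.88 and 9.97. Others lay near Itpr1, an inositol trisphosphate receptor, near Gad1, which makes GABA, within Chmp4c and near Pabpc5. The remaining 3 had no gene end within 100 kb (chromosome 4, 5205454 to 5206310, chromosome 2, 22104934 to 22105706, and chromosome 3, 155487847 to 155488679).

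Regions found in all mutants and neither control were weak, with a top fold of 5.40 in any mutant list. The first by strength (chromosome 2, 12708914 to 12709707) had folds of 4.78, 4.76 and 4.88 in mutants 1, 2 and 3 and no gene end within 100 kb, as had another (chromosome 15, 94004597 to 94005376). The others lay near Zfp982, within Zscan10, within Nphp4 with Kcnab2 as the nearest gene end, at an end of the channel gene Hcn2, near Smad6, an inhibitor of BMP signalling, at ends of Mrgpra3 and C1rb, and near the sensory neuron factor Pou4f1. Of the 42 regions, 6 were gene-end.

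Distal regions of the controls were absent from the mutants far more often than gene-end regions. Among regions present in both controls, each mutant lacked a peak at 57.7% ± 8.5 of 31183 distal regions and at 10.8% ± 5.3 of 13975 gene-end regions (SD, n = 3), a difference of 46.8 ± 3.4 percentage points. Absent from all 3 mutants were 42.0% of distal and 4.64% of gene-end regions. The difference held at like strength in the controls: in the middle of the range, strength decile 5, 39.9% of distal and 8.53% of gene-end regions were absent, and in decile 7, 23.7% and 1.68%. The common odds ratio over the 10 deciles was 6.57 (95% interval 6.0 to 7.2, Cochran-Mantel-Haenszel test). In the strongest decile, 3 of 780 distal and 0 of 3736 gene-end regions were absent from every mutant. The same odds ratio for regions of 1 control absent from the other was 1.31 and 1.52, and 1.47 to 1.94 when that other control was shortened to the length of a mutant list, against 4.25 to 6.16 for the mutants. Between mutants, a comparison added after seeing the data, it was 1.20 to 4.80 over 6 ordered pairs, the highest for regions of mutant 3 absent from mutant 2, whose 95% interval overlaps those for regions of the controls absent from mutants 1 and 3. All 6 comparisons of a mutant with the shortened control had separate 95% intervals. These tests compare regions of these libraries, not embryos, and neighbouring regions are not independent, so the intervals are too narrow.

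**Figure D2:**
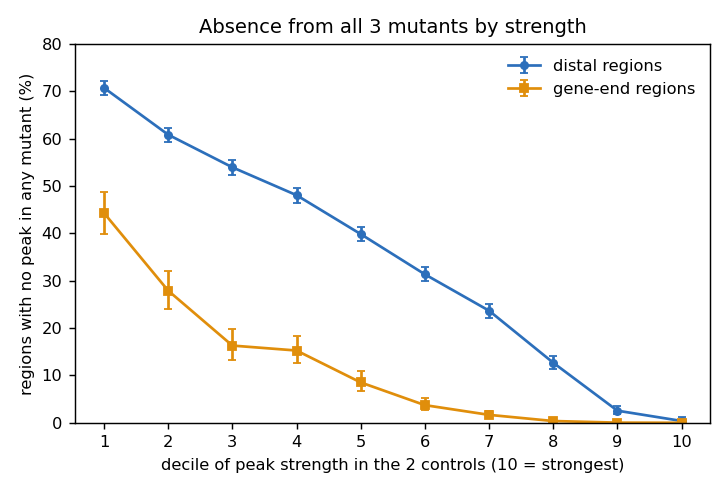
Share of regions present in both controls that had no peak in any of the 3 mutants (percent), by decile of peak strength in the controls, for distal and gene-end regions. Bars are 95% Wilson intervals over regions, and distal regions lie above gene-end regions in deciles 1 to 9, from 70.7% against 44.3% in decile 1 to 2.56% against 0.033% in decile 9.

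**Figure D3:**
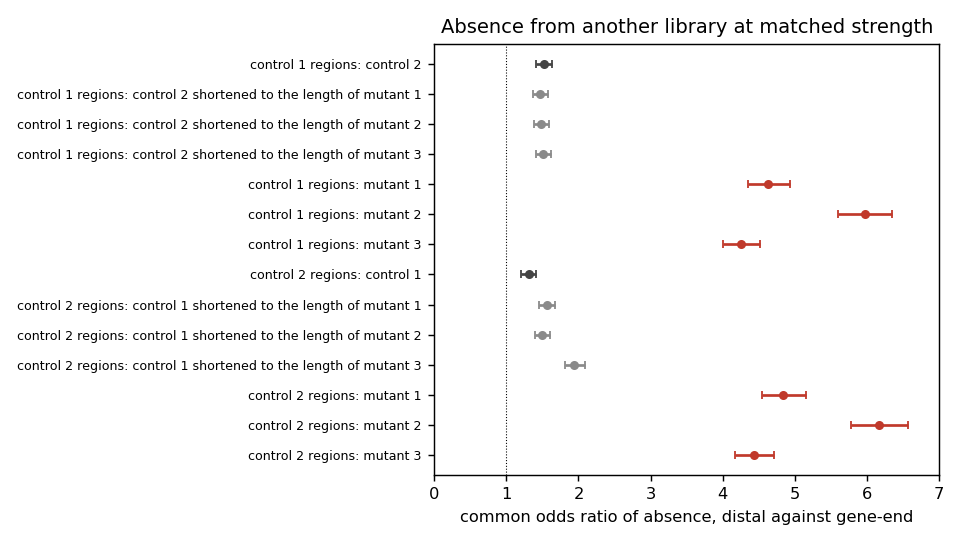
Common odds ratio of absence for distal against gene-end regions, stratified by strength, with 95% intervals (bars). Each row takes the regions of 1 control and asks whether they are absent from the other control (dark), from that control shortened to a mutant's list length (grey) or from a mutant (red), and the mutants lie at 4.25 to 6.16 against at most 1.94 for the rest.

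Hedgehog target genes, the genes the series' question is about, had 1 of 39 gene-end regions and 37 of 104 distal regions absent from every mutant, and no difference from random gene lists was detected. The list test scored only absence of regions present in both controls. It could not detect regions gained or raised in the mutants, so it does not answer the series' question on repression. The 25 listed targets held 143 regions present in both controls, of which 38 (26.6%) were absent from every mutant and 56 were present in all 3. Each mutant held a peak at 56.6% ± 12.3 of the 143 regions (SD, n = 3). Of the list's regions found in control 1, a wider set, control 2 held 70.4%, and of those found in control 2, control 1 held 78.6%. Of the 25 genes, 6 lay above their expected number and 19 below. Such counts need not follow the value of a list. Among lists above their random median, the endothelial list (2.73 points) had 4 genes above and 15 below, and WNT (5.90 points) 12 and 8. The stratified absence of the Hedgehog targets minus the median of random gene lists was -3.45 points (adjusted p = 0.838, permutation over genes, Benjamini-Hochberg adjustment over 23 lists). The sign turned under 6 other settings, none of which passed the test, and with assignment by gene body with flanks on both sides, where the plan had the upstream side alone, the value was -11.3 points (unadjusted p = 0.017, adjusted p = 0.0782, permutation over genes).

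Of the direct readouts of Hedgehog signalling, Gli1 had both of its regions in all 3 mutants. Ptch1, which encodes the Hedgehog receptor (chromosome 13, 63508328 to 63573460), had 7 regions: a gene-end region (63572136 to 63574025) and a region in the gene body (63562901 to 63569506) were present in all mutants, and a region in the gene body (63535137 to 63535849) and one 69.4 kb outside the gene (63642607 to 63643499) were absent from all. Hhip, a Hedgehog antagonist, had 4 of 5 absent, with a gene-end region (chromosome 8, 80057037 to 80058164) present in all mutants. Another Hhip gene-end region (80058412 to 80058873) was among the absent ones. The absent Hhip regions were weak, with folds of 2.77 to 3.81 in the controls. The BMP antagonist Grem1 had 1 assigned region, present in all mutants. No region was absent from every mutant at Ccnd2 (5 regions), Tbx2 (7), Tbx3 (5), Foxc2 (2), Hoxd10 (4), Hoxd11 (3), Hoxd12 (2) or Hoxd13 (2). Present in all mutants were 4 of these at Ccnd2, 3 at Tbx2, 1 at Tbx3, both at Foxc2, 2 at Hoxd10 and 1 each at Hoxd11, Hoxd12 and Hoxd13. The rest held a peak in only 1 or 2 mutants. The posterior limb factor Hand2 had 2 of 12 absent, the kinase gene Pkdcc 4 of 15, Bmp2 4 of 10, Mycn 5 of 8, Foxf1 3 of 8, Sall1 3 of 8, Jag1 2 of 8, Rasgef1b 3 of 7, Prdm1 2 of 5, Osr1 1 of 5, Cntfr 1 of 5 and Ccnd1 1 of 4. At Mycn the 5 absent regions were intergenic and the gene-end region was present in all mutants.

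**Figure D4:**
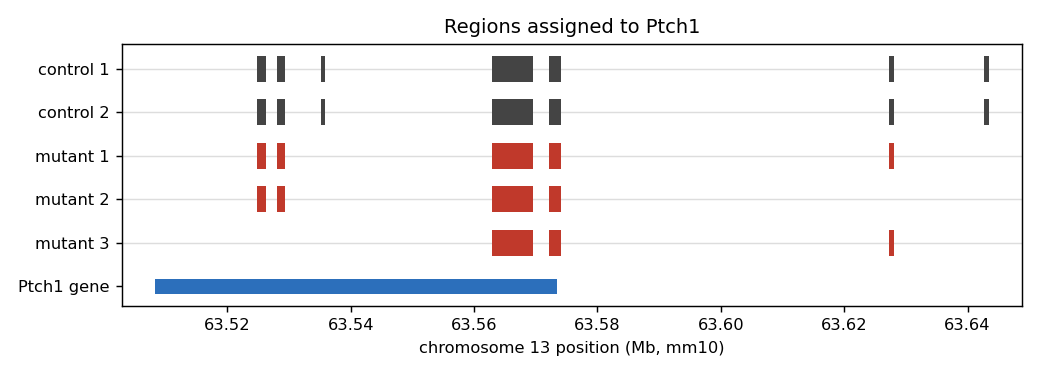
Regions assigned to Ptch1 and present in both controls (boxes, drawn to scale with a minimum width) along chromosome 13 in Mb (mm10), shown in each library that held a peak there, with the gene body in blue. Of the 7 regions, 2 were present in all 3 mutants, 2 in none and the other 3 in 2 mutants.

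Genes of the Hedgehog pathway itself had 38 of 113 regions absent from all mutants (33.6%, adjusted permutation p = 0.867). Gli2 had 11 of 29 absent, Gli3, the source of the main repressor (chromosome 13, 15463723 to 15730026), 8 of 21, the co-receptor Boc 6 of 13 and Gas1 4 of 12, while Smo had all 4 of its regions in every mutant. BAF subunit genes had 20 of 82 absent (24.4%, adjusted permutation p = 0.974). Arid1b had 7 of 16 absent, Brd7 3 of 4 and the ATPase gene Smarca2 3 of 6.

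Limb patterning lists had fewer absent regions than expected from strength and class, as had the median random list, and none of them passed the test after adjustment. The 5 lists lay 6.50 to 13.9 points below the median of their random lists, which itself lay 1.97 to 2.92 points below that expectation. They share members, such as Hoxd13 in the posterior, distal and Hox lists and Irx3 in the anterior and proximal lists. Their common direction is thus partly the same regions counted more than once. Under other settings the anterior list turned to more absence in 3 and the proximal list in 2. Hox A and D cluster genes had 7 of 76 regions absent from all mutants, 9.21% against 25.9% expected (p = 0.0074, adjusted permutation p = 0.17). Of 22 genes, 21 lay below expectation. The genes of each cluster lie side by side, while the test draws genes as independent units, so this p and count may overstate the evidence. The regions were found at 68.4%, 88.2% and 38.2% in mutants 1, 2 and 3, so mutant 3 lacked most of them. The deficit rested on mutant 2: without it the permutation p over genes was 0.902 (adjusted 0.992). Across the settings the adjusted p ran from 0.00548 to 0.992, past the threshold in 3 of them. By permutation over genes these were without control 1 (0.0368) and at a −log10 q of at least 10 (0.0069). The last was without stratification (0.00548, Fisher's exact test over regions, which treats the regions of a gene as independent). At a −log10 q of at least 5 the permutation p was 0.229. Posterior limb genes had 9 of 64 absent (14.1%, p = 0.0486, adjusted permutation p = 0.336), distal limb genes 18 of 85 (21.2%, adjusted permutation p = 0.336), proximal limb genes 18 of 77 (23.4%, adjusted permutation p = 0.456) and anterior limb genes 28 of 91 (30.8%, adjusted permutation p = 0.703). Examples from these lists are Hoxa13 with 2 of 11 absent, Tbx15 with 1 of 10, Lhx9 with 2 of 9, Asb4 with 4 of 9 and Alx4 with 3 of 6.

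Genes of limb mesenchyme, the tissue in which the Cre acts, had 24 of 113 regions absent (21.2% against 33.1% expected, adjusted permutation p = 0.336). Tbx5, the forelimb identity factor, had 7 of 21 absent, Twist2 5 of 8 and Col1a2 0 of 7. Chondrogenesis genes had 33 of 85 absent (38.8% against 38.0% expected, adjusted permutation p = 0.867). Sox5 had 6 of 11 absent, Sox6 5 of 9, Runx3 5 of 12 and the cartilage regulator Sox9 3 of 7. Without stratification by strength the chondrogenesis list had an adjusted p of 0.0384 (Fisher's exact test), the lowest of a range up to 0.993 over the settings.

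Among signalling lists, WNT genes had 51 of 133 regions absent (38.3% against 35.4% expected, adjusted permutation p = 0.672). Lef1 had 8 of 13 absent, Tcf7l1 and Tcf7l2 6 of 13 and 6 of 17 and Axin2 2 of 11. Without stratification the adjusted p of the WNT list was 0.00755 (Fisher's exact test over regions, not genes), the lowest of a range up to 0.977. FGF genes had 32 of 102 absent (31.4%, adjusted permutation p = 0.944), with the receptor Fgfr2 at 11 of 15 and Spry2, an FGF feedback inhibitor, at 0 of 7. BMP genes had 35 of 135 absent (25.9%, adjusted permutation p = 0.805), with Bmp7 at 7 of 17, Chrdl1 at 4 of 7 and Msx1 at 2 of 9. Retinoic acid genes had 29 of 95 absent (30.5%, adjusted permutation p = 0.867), with Dhrs3 at 7 of 11, Aldh1a2, which makes retinoic acid, at 5 of 6, and Nr2f2 at 2 of 10.

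Marker genes of other cells of the limb bud showed no list past the threshold. Neural crest and glia markers had the highest absence, 22 of 44 regions (50.0% against 37.1% expected, p = 0.0502, adjusted permutation p = 0.336), with Tfap2a at 6 of 12 and Mitf at 4 of 7. Without stratification the adjusted p of this list was 0.00548 (Fisher's exact test over regions, not genes), the lowest of a range up to 0.993. Muscle precursor markers had 22 of 54 absent (40.7% against 40.8% expected, adjusted permutation p = 0.903), with Eya1 at 6 of 8. At a −log10 q of at least 10 the muscle list had an adjusted p of 0.0069, towards more absence, the lowest of a range up to 0.998. Endothelial markers had 23 of 63 absent (36.5% against 36.7% expected, adjusted permutation p = 0.867), with Fli1 at 7 of 11 and Cdh5 at 1 of 6. Ectoderm markers had 22 of 73 absent (30.1% against 33.3% expected, adjusted permutation p = 0.974), with Sp8 at 3 of 8 and Dlx5 at 0 of 6. Blood markers had 14 of 44 absent (31.8% against 36.3% expected, adjusted permutation p = 0.985), of which Runx1 gave 9 of 15.

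Of the remaining lists, housekeeping genes had 3 of 55 regions absent (5.45% against 17.9% expected, adjusted permutation p = 0.336), with Ywhaz at 1 of 10. Without stratification their adjusted p was 0.0037 (Fisher's exact test over regions, not genes), the lowest of a range up to 0.862. Cell cycle genes had 16 of 78 absent (20.5%, adjusted permutation p = 0.903), with Cdk6 at 3 of 6 and Ccne1 at 1 of 7. For p53 and apoptosis genes it was 15 of 54 (27.8%, adjusted permutation p = 0.867), with Pmaip1 at 4 of 9, and for genes of unrelated organs 6 of 26 (23.1%, adjusted permutation p = 0.838), with Snap25 at 2 of 4. With 0 of 23 lists past the adjusted threshold and 2 at an unadjusted p under 0.05, the permutation test over genes set no list apart. In simulated lists of 20 genes with 10 points of added absence, 61 of 100 passed the unadjusted threshold, so differences of that size are often missed. The simulation drew each region on its own, took only genes with at least 3 regions and made no adjustment over lists. Many listed genes have fewer regions. It thus does not give the power of the adjusted calls, nor that of lists with such genes.

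**Figure D5:**
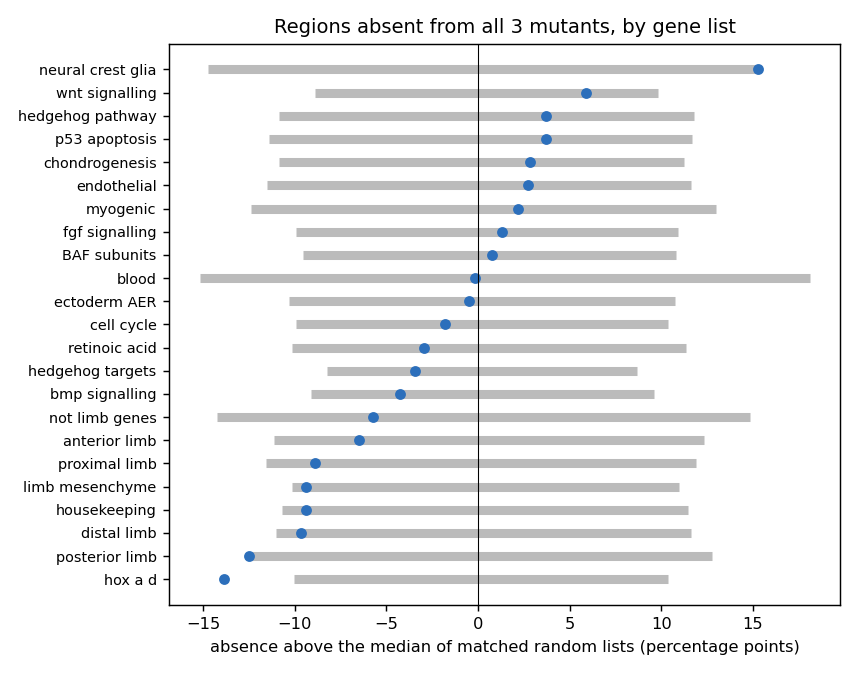
Share of regions absent from all 3 mutants for each gene list, as percentage points above the median of random gene lists matched on regions per gene (points), after removing the rate of each stratum of strength and class. Grey bars hold the central 95% of random lists, and only the Hox A and D, posterior limb and neural crest lists lie at or beyond a bar's end, with adjusted p of 0.17, 0.336 and 0.336.

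Single genes differed widely in how many of their regions were absent. Of genes with at least 5 regions in both controls, the largest excess over expectation was at Trabd2b, a WNT protease (18 of 29 regions absent, 12.1 expected), followed by the kinase gene Fyn (12 of 15), Fgfr2 (11 of 15, 6.29 expected), App (9 of 13) and Zswim6 (10 of 17). The largest deficit was at Lmx1b, the dorsal limb determinant (chromosome 2, 33560965 to 33641208), with 3 of 23 absent and 9.85 expected, followed by Gse1 (3 of 25), Gins2 (7 of 29), Bahcc1 (1 of 21) and Septin9 (6 of 28). Gse1 and Gins2 overlap on chromosome 8 (120228501 to 120581383 and 120581266 to 120589075). Assignment by the nearest end divides the regions around them, so their deficits are not separate. All these genes are the extremes of a ranking and carry no test of their own.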

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

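Control lists shortened to each mutant list gave 4.71 points of gene-end share, against 16.6 in the main comparison and 4.42 at equal length. That setting and the class of a region by its summit (odds ratio 6.46) were chosen after seeing the data. All other settings were fixed before, but the gene table without strand changed the plan. In the main analysis promoters became gene-end regions, and the nearest end replaced the nearest start. Among the alternatives, the nearest end also replaced the nearest start within 20 kb. Gene bodies had 5 kb flanks on both sides in place of the upstream side alone. The odds ratio of absence for distal against gene-end regions stayed above 1 in every setting, from 4.60 (summit windows) to 20.4 (asymmetric threshold), and the lower peak number and covered length of the mutants kept their direction wherever computed. Equal list lengths fix the peak number and give it no value, and there the median width difference reversed to -270.5 bp (mutant minus control; main value 27.7). The Hedgehog target list, at -3.45 points with no call, reversed to 0.587 at a −log10 q of at least 10, 2.80 at 5, 0.298 at equal length, 5.62 at a fold of at least 5 and 1.32 with summit windows, turned sign without stratification, and stood at -11.3 by gene body with 5 kb flanks (adjusted p = 0.0782, permutation over genes), again with no call; the cause was not tested. Regions in the controls alone (13743) numbered 4732 at a −log10 q of 10, 1537 with the asymmetric threshold, 2976 at equal length, 3276 at a fold of 5 and 14399 to 31736 without 1 library. Regions in the mutants alone (42) numbered 9 and 18 at a −log10 q of 10 and 5, 1 with the asymmetric threshold, 677 at equal length, 11 at a fold of 5, 385 with summit windows and 114 to 440 without 1 library. Regions in all 5 libraries (19579) numbered 10073 at a −log10 q of 10 and 9423 at a fold of 5, where fewer peaks enter. The overlap between genotypes (0.460) was 0.528 at a −log10 q of 10, 0.566 at equal length and 0.544 at a fold of 5, and as a share of the shorter list 86.1% by 1 bp and 81.7% by at least 50% of the peak, above the means within controls (80.6% and 74.6%) and within mutants (84.9% and 79.9%). Gene lists with less absence (0) numbered 1 at a −log10 q of 10, 2 without stratification and 0 to 1 without 1 library (1 without control 1). Lists with more absence (0) numbered 1 and 3 in the first and second of these. Without stratification the test also changed, from permutation over genes to Fisher's exact test over regions. The cause was not tested. The 27 motif tests were not run in any setting. No paired analysis was possible because replicate numbers only follow sample order. Background levels limit the lists to folds above 2.29 to 2.52, so weaker accessibility was not detectable. The lowest fold was slightly higher in each mutant than in either control.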

Other observations

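The tests of sequenced fragments, of enrichment at housekeeping genes, of mesenchyme share, of absence between mutants and of peaks in mutant 2 alone were chosen only after the result was seen.

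Absence from the mutants rose with distance from gene ends. Of distal regions in both controls, 23.6% of 5238 were absent from all mutants within 5 kb of a gene end, 32.5% at 5 to 20 kb, 44.2% at 20 to 50 kb, 52.0% at 50 to 100 kb and 61.0% of 6239 beyond 100 kb. A few gene-end regions with strong control peaks were absent too, named here after their values were seen: Cep152, a centriole gene (chromosome 2, 125548546 to 125549569, folds 8.15 and 8.35), Slc26a7, Gpr165, Nln and Anxa5. By chromosome, absence ran from 20.7% on X to 36.6% on chromosome 3. Against regions of like strength and class, X stood at -0.068 points, chromosome 3 at 6.20, and the 5 chromosomes densest in genes (2, 7, 11, 17 and 19) between -5.28 and -0.994.

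Mutant libraries had fewer peaks than controls. Fewer sequenced fragments are neither shown nor excluded. In 3 of 6 pairs of a mutant and a control the mutant had the higher background level, as all mutants lay above control 1 and below control 2. Peak number did not follow this level: control 1 had the lowest level and the most peaks (68959), control 2 the highest level and 60333 peaks. The level measures depth only if fragments were extended alike. Weaker enrichment stays open: at 11355 gene-end regions found in all 5 libraries the median fold was 8.84 and 8.22 in the controls and 6.94, 8.05 and 6.22 in the mutants, and at 26 housekeeping regions it was 9.36 and 9.50 in the controls and 8.33 and 7.07 in mutants 1 and 3. In mutant 2 the housekeeping median was 9.85, above both controls, while the wider set lay below them, so weaker enrichment is neither shown nor excluded for that library. At 8224 distal regions found in all 5 libraries all mutants lay below both controls (6.24 and 5.52 against 4.94, 4.93 and 4.21), as weaker enrichment or less accessible distal regions would both give. Whether fewer regions were open without BAF155 was not tested, since these folds are scaled within each library. Chromatin of another species added in equal amount to each sample would decide it.

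Distal regions were absent from mutants more often than gene-end regions of like strength. Weaker enrichment that only shortens the list does not account for this, since in 6 of 6 comparisons the odds ratio to a mutant lay above that to a control shortened to the same length, with separate intervals. Ordinary variation of distal regions stays open. The odds ratio to a mutant lay above that to the other control in 6 of 6 comparisons, but these rest on 1 pair of controls. Between mutants it was 1.20 to 4.80 over 6 ordered pairs. The highest lay within the range for regions of controls absent from mutants (4.25 to 6.16), so the planned bound from the control pair was too low. For regions of a mutant absent from a control the odds ratio was 1.06 to 2.85. A smaller share of mesenchyme stays undecided. It would raise absence at mesenchyme genes only if their regions are open mainly in that tissue, which peaks from mixed cells do not show. Stratified absence at mesenchyme genes minus that of pooled markers of other cell types was -12.3 points (p = 0.0312 by permutation over genes). The random range was -11.3 to 12.2, so the margin was close to the edge. That distal elements depend more on BAF155 than gene ends is a hypothesis that these data do not set apart from variation between embryos. More embryos of each genotype, with BAF155 binding mapped in controls, would decide it.

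The rise with distance held at like strength, by 36.8 points of stratified absence from all mutants, from the nearest to the farthest bin. The rise was also taken in shares absent from 1 library, not matched for strength. Between the controls it was 0.547 and -9.62 points and between mutants -18.8 to 11.6. From controls to mutants it was 15.8 to 30.8, and from mutants to controls -25.0 to -4.01. By this unmatched measure, more variable regions far from gene ends do not account for all of the rise from controls to mutants. Adjacent distal regions within 50 kb shared their fate (r = 0.188 across regions, 0.0274 at most in 1000 shuffles, permutation p = 0.001, the smallest they can give), though regions are not independent replicates. Absence may thus run over stretches of chromosomes, and whether distance or the stretch sets it was not tested.

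Mutant 2 held 6965 regions found in no other library, against 1994 and 682 in mutants 1 and 3, and 37.3% of them lay on the 5 chromosomes densest in genes, 10.8 points above those of control 1 alone. For regions of control 2, mutant 1 and mutant 3 alone the share was 30.0%, 32.5% and 32.0%, and for all peaks of mutant 2 it was 32.6%.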
